A study of Mus musculus with 8 samples.

How the data were processed

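RNA bound to the cytoplasmic polyadenylation element binding proteins CPEB1 and CPEB4 was measured in mouse striatum by RNA immunoprecipitation (RIP), in which an antibody pulls down a protein with the RNA crosslinked to it. Per the labels, striatum of male WT and HD mice aged 7 to 8 months was pooled by genotype, with 4 mice named in the design text, crosslinked with formaldehyde and lysed. An aliquot of the lysate was kept as input. The rest was precipitated with antibody against CPEB1, with antibody against CPEB4, or with IgG of rabbit, the control for RNA that sticks to beads and antibody. The labels' protocols give amplification of the RNA over 27 cycles and 8 µg of cDNA per array. Each of the 4 fractions of the 2 genotypes has 1 array, so there are 8 arrays and no replicate within a group. The labels do not spell out HD, and what it stands for is not given in the sources used here.

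The deposited values are log2 probe set summaries made with RMA, a background correction, normalization and summary of Affymetrix probes, per the submitters' processing notes; its version, and whether the 8 arrays were run together, are not given in the sources used here. The values were used as deposited, with no further scaling. Of 45101 probe sets, 28898 were named with 1 gene symbol, 551 with several and 15652 with none in the platform annotation; symbols of 28689 were matched through the RefSeq gene table of assembly GRCm38.p6. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. Each of 17097 genes was represented by its single-symbol probe set with the highest mean over the 8 arrays, and the 11345 genes whose mean lay above 4.23, the median of all probe set means, were tested. For arrays the number of arrays limits the precision.

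Fractions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, two-sided, Benjamini-Hochberg adjusted p under 0.05). The model held fraction and genotype pool, the block, over all 8 arrays, which leaves 3 residual degrees of freedom, with 2.29 from the prior. The pools stand in for replicates, so binding that differs by genotype counts as error. The block removes the mean difference between the 2 pools, which were amplified separately. The p-values measure how unevenly the 4 fractions differ between the pools, and so rest also on fractions outside a comparison. An error is the standard error (SE) of that model. The same model tested on simulated arrays, for CPEB4 RIP against IgG RIP over 11345 genes with 200 changed genes, recovered 92% of changes of 4 on the log2 scale, with 8.8 false among 192.8 called on average over 5 runs, and 0% of changes of 1 or 2. These rates need not hold for the data, where 2598 genes had an unadjusted p under 0.05 by limma and called folds went down to 1.72. The simulation also had no difference in spread between fractions. Differences between HD and WT rest on 1 array each and were not tested; genes were counted at a log2 difference of 1 (2-fold).

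The 21 gene lists covered medium spiny neurons, the other cell types of striatum and neighbouring tissue, synapses, cytosolic ribosomal proteins, oxidative phosphorylation, immediate early genes, poly(A) and 3′ end factors, thiamine use, nuclear long noncoding RNA, autism genes, neurodegeneration genes and reported CPEB targets. They were tested with camera in limma at a preset correlation of 0.01 and at an estimated one. For single-array differences a list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The tests, gene rule, lists, named genes and all alternatives except those said below to have been added were chosen before the data were examined. Named genes were, for each antibody over IgG, the 10 largest log2 folds up and 5 down among genes past the test with the same sign in both pools, filled up by size among genes at 2-fold in both pools; 6 each way between the antibodies; 6 each way for HD minus WT enrichment among genes at 2-fold over IgG in at least 1 genotype; 10 each way for input; up to 4 members of each list by absolute value; and Cpeb1, Cpeb2, Cpeb3, Cpeb4, Htt and Slc19a3. Clone and predicted-gene identifiers were passed over. List members named beyond the 4 largest, because they passed the test, were chosen after their values were seen. Comparisons that share an IgG array were set beside 100 simulations of unchanged arrays.

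The alternatives were no filter or a 75th percentile filter, the mean of a gene's probe sets or all probe sets, cyclic loess or median centring, no block, trended robust eBayes, only the arrays of the 2 fractions compared, leaving out each array, fold thresholds of 1.5 and 3, and input in place of IgG. Quantile normalization, and the mean of both pools as the background for enriched genes, were added after seeing the data. A planned search of 3′ untranslated regions for the polyadenylation element was not run, since no genome sequence was used here.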

Results

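RNA from 4 fractions of striatal lysate, the input and the anti-CPEB1, anti-CPEB4 and IgG precipitates, was hybridised to 8 arrays, 1 per fraction for the WT pool and 1 for the HD pool. Over the 11345 genes the CPEB4 arrays spread most widely within each pool, with an SD of 1.8 in WT and 1.69 in HD on the log2 scale. The others had 1.71 and 1.44 for CPEB1, 1.43 and 1.55 for input, and 1.46 and 1.36 for IgG. Of the 11345 genes the CPEB4 arrays held 1810 and 1553 above a value of 8, against 924 and 648 for IgG. Medians over all probe sets lay between 4.03 and 4.28 on all 8. The spike-in control probe sets had their lowest means on the CPEB4 arrays, 9.28 and 9.76, against 10.12 to 10.77 on the other 6. Across genes, which are not independent replicates, the CPEB4 arrays of the pools correlated at r = 0.899, the CPEB1 arrays at 0.813, the inputs at 0.792 and the IgG arrays at 0.778.

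Which striatal mRNAs came down with CPEB4 was asked first, against IgG. In both pools the CPEB4 precipitate held far more RNA of Zfp365 (log2 5.44 ± 0.80 SE, 43.3-fold, n = 2 pools, adjusted p = 0.043). Nearly as large were the folds of Cds2, which makes CDP-diacylglycerol for phosphoinositide synthesis (5.43 ± 0.53, adjusted p = 0.0351), and of Sumo2, a ubiquitin-like modifier (5.41 ± 0.75, adjusted p = 0.0406). Grm5, the metabotropic glutamate receptor mGluR5, was 29.6-fold higher (log2 4.89 ± 0.52, adjusted p = 0.0367), and Spred1, an inhibitor of Ras-MAP kinase signalling, 25.4-fold higher (4.66 ± 0.38, adjusted p = 0.0259). Fam76b (5.0 ± 0.24), Ivns1abp (4.89 ± 0.40), Rpl34-ps1 (4.73 ± 0.62), Zfp622 (4.69 ± 0.54) and Zcchc3 (4.69 ± 0.60) completed the 10 largest. The 5 genes lower in the CPEB4 precipitate were Lgals2, a galectin (-5.19 ± 0.28), Xbp1, a transcription factor of the unfolded protein response (-3.08 ± 0.44), Dus3l (-2.50 ± 0.31), S100a11 (-2.21 ± 0.34) and Dppa2 (-1.84 ± 0.28). Of the 10 genes higher, Zfp365, Cds2, Fam76b, Ivns1abp, Zfp622, Zcchc3 and Spred1 had IgG values below 4.23, the median of all probe set means, in both pools, so the sizes of their folds depend on the array background. On the IgG arrays Lgals2 stood at 9.76 and 10.58, against 4.81 to 5.78 on the other 6. Xbp1 (6.50 and 8.33 on IgG, at most 4.85 elsewhere), Dus3l, S100a11 and Dppa2 were likewise higher on both IgG arrays than on all others. With CPEB4, Xbp1 (3.82 and 4.85) was not below input (3.60 and 3.85).

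By limma 264 genes were higher and 5 lower, the smallest called fold being 1.72 on the log2 scale, and all 269 had the same sign in both pools. At an unadjusted p under 0.05 there were 2598 genes, 1781 of them higher, where chance gives 567. Other probe sets of Spred1 (4.57 and 5.02, 4.30 and 3.22, 2.81 and 2.39 in WT and HD), Ivns1abp (4.55 and 3.54) and Sumo2 (2.05 and 1.68) were also above IgG in both pools. The other 4 Cds2 probe sets had 2.87 and 2.51, 1.18 and 0.99, 0.11 and 2.35, and -0.62 and 2.47. The other 2 of Zfp622 had 1.20 and 0.49 and 0.04 and 2.47, and the second Xbp1 probe set had 0.23 and -0.65. The adjusted call was lost in all genes after quantile normalization, which moved the median of all genes from -0.065 to -0.25 and the unadjusted split to 1095 higher and 1505 lower; median centring moved that median to 0.096. It was lost too with only the CPEB4 and IgG arrays in the fit, where the 264 genes had a median log2 of 2.91 ± 0.29 and a median adjusted p of 0.0838 by limma. Without any 1 of the CPEB4, IgG or input arrays it was also lost; a fraction left with 1 array is then taken to vary like the others.

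**Figure D1:**
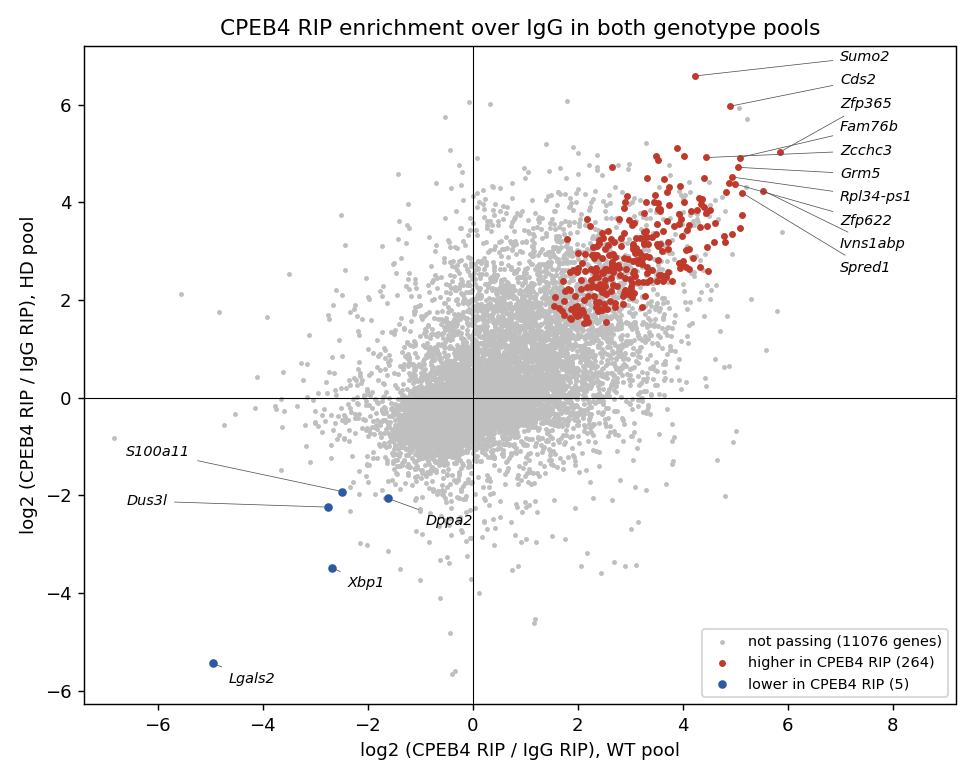
Each point is 1 of 11345 genes, with log2 CPEB4 RIP over IgG RIP in the WT pool on the x axis and in the HD pool on the y axis; red points are the 264 genes higher and blue points the 5 lower by limma. The called genes lie in the upper right, with Sumo2 at 4.23 and 6.59 and Cds2 at 4.90 and 5.97, and Lgals2 at -4.95 and -5.44 in the lower left.

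**Figure D2:**
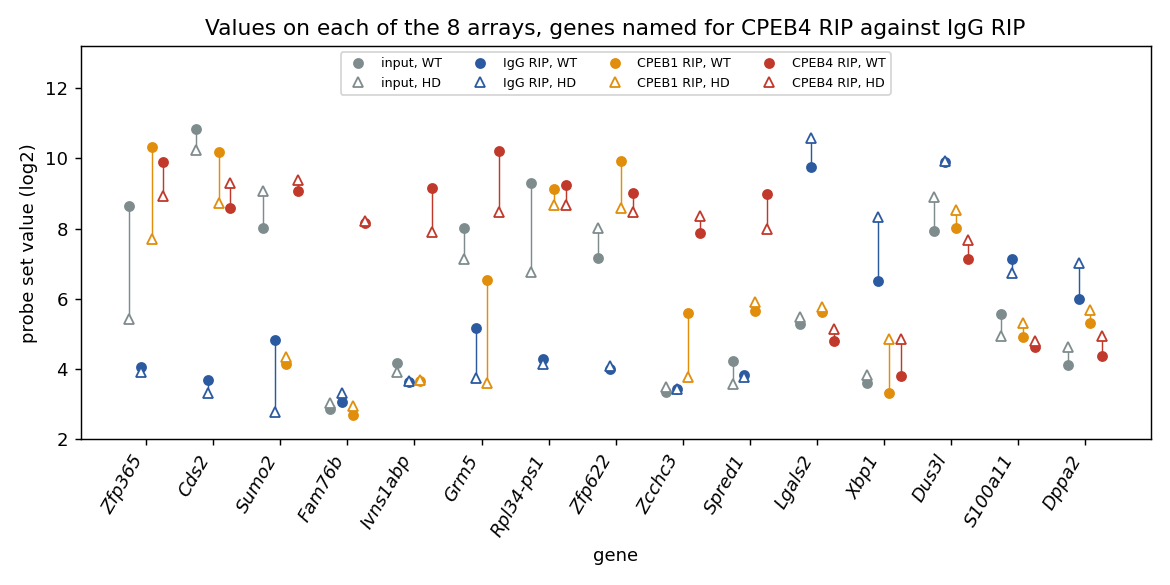
Log2 probe set values on each of the 8 arrays for the 15 genes named for CPEB4 RIP against IgG RIP, with filled circles for WT, open triangles for HD and a line joining the pools of a fraction. Fam76b stands at 8.16 and 8.23 on the CPEB4 arrays and at 2.69 to 3.31 on the other 6, while Cds2 is also high in the input, at 10.85 and 10.24.

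Among the lists, factors that act on poly(A) tails and mRNA 3′ ends had the most called members. Of 35 measured, 6 were higher with CPEB4 over all genes tested and 10 adjusted over the list alone, and none was lower. They were Pabpc1, the cytoplasmic poly(A) binding protein (3.98 ± 0.33, adjusted p = 0.0259), Pum2, a Pumilio RNA-binding repressor (3.33 ± 0.29, adjusted p = 0.0263), the CCR4-NOT deadenylase subunits Cnot8 (3.52 ± 0.46), Cnot7 (3.05 ± 0.47) and Cnot6 (3.0 ± 0.43), and Tnrc6b, of microRNA silencing (2.87 ± 0.43). The list's median was 0.98, at percentile 100 of matched random lists, with camera adjusted p = 9.96e-06 (adjusted p = 0.407 with an estimated correlation). Autism genes had a median of 1.28, also at percentile 100 (camera adjusted p = 0.00191; adjusted p = 0.481 with an estimated correlation). Of 43 measured 2 were higher over all genes tested, Tnrc6b and the histone methyltransferase Kmt2c (2.27 ± 0.28), and 8 adjusted over the list alone. Wdfy3 (3.37 ± 0.61) and Cul3 (3.33 ± 0.89) did not pass over all genes. Under cyclic loess, at the preset correlation, both lists passed (adjusted p = 5.79e-05 and 0.0328); after quantile normalization their medians were 0.40 and 0.70.

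Synaptic genes were also higher as groups in camera at the preset correlation, though not with an estimated one (adjusted p = 0.481), and within the central 95% of random lists matched on expression. Of 35 measured postsynaptic genes (median 1.01, percentile 96.1, adjusted p = 9.96e-06), Grm5 and the GABA-A receptor subunit Gabra2 (4.0 ± 0.45) passed over all genes and 8 adjusted over the list alone; Arc (3.48 ± 0.77) and Gria2 (3.18 ± 0.72) did not pass over all genes. Of 35 presynaptic genes (median 0.81, percentile 77.4, adjusted p = 0.000146), the active-zone protein gene Erc2 (3.25 ± 0.32), Syt4 (2.67 ± 0.34) and Syngr3 (2.22 ± 0.29) passed, and 7 adjusted over the list alone. Of 39 markers of medium spiny neurons, the projection neurons of striatum (median 1.04, percentile 95.5, adjusted p = 1e-04), Tmem158 (2.55 ± 0.27) and Kcnip2 (2.33 ± 0.32) passed, and 10 adjusted over the list alone. Immediate early genes had a median of 1.08 (percentile 99, adjusted p = 0.0345, 0 of 12 passing and 3 adjusted over the list alone) and oligodendrocyte genes 0.64 (percentile 73.6, adjusted p = 0.0348, 0 of 14 passing and 2 adjusted over the list alone). Cytosolic ribosomal protein genes had a median of 1.04 (percentile 79.7, adjusted p = 2.4e-06; Rps19, 3.53 ± 0.50, passed of 65, and 3 adjusted over the list alone), which turned to -0.32 under cyclic loess. After quantile normalization the medians were 0.35 for postsynaptic, 0.10 for presynaptic, 0.36 for medium spiny neuron, 0.49 for immediate early, 0.28 for oligodendrocyte and 0.51 for ribosomal genes. With an estimated correlation none of these 6 lists passed (adjusted p = 0.481 for each). Under cyclic loess the synaptic, medium spiny neuron, immediate early, oligodendrocyte and ribosomal lists did not pass either.

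The remaining lists did not pass camera for CPEB4 over IgG. Reported CPEB targets (median 0.31, adjusted p = 0.163) held 2 called genes of 24, Sumo2 and the dendritic cytoskeletal gene Map2 (2.43 ± 0.35), and 3 adjusted over the list alone, with a median of -0.01 after quantile normalization. Neurodegeneration genes (median 0.85, adjusted p = 0.0514) held 1 of 26, the autophagy gene Becn1 (3.30 ± 0.44), with a median of -0.07 after quantile normalization. Endothelial and mural genes (median -0.38, adjusted p = 0.195) held 1 of 14, the glucose transporter Slc2a1 (3.46 ± 0.49). Oxidative phosphorylation genes had a median of 0.38 with 0 of 68 called (adjusted p = 0.189), at percentile 1.29 of random lists matched on expression. Their median turned to -0.37 under cyclic loess, where the list passed as lower (adjusted p = 0.0496), and to -0.43 after quantile normalization. Nuclear long noncoding RNAs had a median of -0.87 (adjusted p = 0.14), at percentile 0, but 0.15 for CPEB4 against input. Medians of the other lists were 1.09 for thiamine use (adjusted p = 0.295; 0.14 after quantile normalization), 1.01 for cortical excitatory neurons (0.14), 0.69 for astrocytes (0.14; 0.09 after quantile normalization), 0.23 for oligodendrocyte precursors (0.355; -0.06 after quantile normalization), 0.08 for striatal interneurons (0.717; -0.19 after quantile normalization), -0.10 for microglia (0.397; 0.16 under cyclic loess), -0.39 for choroid plexus and ependyma (0.14) and -0.59 for blood (0.185).

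**Figure D3:**
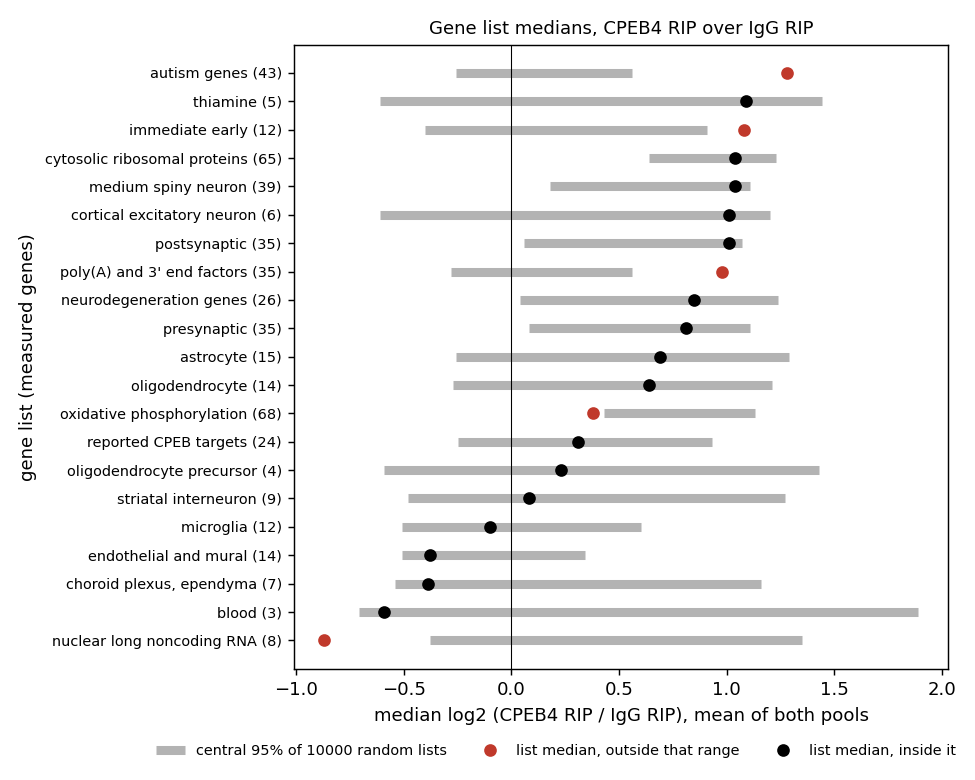
Median log2 CPEB4 RIP over IgG RIP, averaged over both pools, of each of the 21 gene lists (points, x axis), with the central 95% of 10000 random lists matched on mean expression as grey bars and the number of measured genes in brackets. Autism genes (1.28), immediate early genes (1.08) and poly(A) and 3′ end factors (0.98) lie above their bars, and oxidative phosphorylation genes (0.38, but -0.37 under cyclic loess) and nuclear long noncoding RNAs (-0.87) below.

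Against input the CPEB4 precipitate was higher most of all for Cenpb, which binds centromeric DNA (log2 5.84, adjusted p = 0.0229), Trim44 (5.39, adjusted p = 0.0353) and Pdlim5 (5.34, adjusted p = 0.0353), and again for Fam76b (5.24, adjusted p = 0.0229). By limma 152 genes were higher and 2 lower, Dhrs1 (-2.44 ± 0.33, adjusted p = 0.0469) and Masp1 (-1.90 ± 0.24, adjusted p = 0.0411), and 2967 had an unadjusted p under 0.05. After quantile normalization 0 genes passed, and the unadjusted split was 1092 higher and 1593 lower. Of the 264 genes higher over IgG, 109 also passed against input and 247 lay above input in both pools. The 2 comparisons share the CPEB4 arrays: unchanged arrays in simulation gave 51.3 and 181 for lists of these sizes, and independent lists 3.54 and 79.3. Against input CPEB1 was higher for Cenpb (6.04 ± 0.33) and Mrps33 (4.78 ± 0.25), with 0 genes lower and 916 at an unadjusted p under 0.05. IgG was higher than input for Lgals2 (4.78 ± 0.28) and Mrps33 (5.04 ± 0.25) and lower for Sec14l1 (-4.85 ± 0.29), with 1106 genes at an unadjusted p under 0.05. IgG stood above input for Cenpb (4.35, adjusted p = 0.0542), Pdlim5 (4.95, adjusted p = 0.103) and Trim44 (2.34, adjusted p = 0.227) too. For Pdlim5 CPEB4 was only 0.39 above IgG (adjusted p = 0.594). The genes named for input were chosen after their values were seen. Nuclear long noncoding RNAs were higher in IgG than in input as a list (median 0.74, camera adjusted p = 0.00252, 0.596 with an estimated correlation). Without any 1 array these 3 counts against input were 0.

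For CPEB1 no gene passed against IgG. The largest folds were those of Cds2 (log2 5.95 ± 0.53, adjusted p = 0.121), Zfp622 (5.20 ± 0.54, adjusted p = 0.121), Ppp1r12b, a myosin phosphatase subunit (5.14 ± 0.78), Zfp365 (5.03 ± 0.80), Eef1g (4.90 ± 1.12), Pdzd4 (4.70 ± 0.38), Rpl34-ps1 (4.69 ± 0.62), Wsb2 (4.62 ± 0.94), Samd14 (4.58 ± 0.77) and Rdh11 (4.51 ± 0.53). Downward they were Lgals2 (-4.47 ± 0.28), Sprr2a1 (-4.0 ± 1.6), Ddx5 (-3.94 ± 0.64), Pdlim5 (-3.92 ± 0.47) and Ssr3 (-3.82 ± 0.79). Cds2, Zfp622, Zfp365 and Rdh11 had IgG values below 4.23 in both pools, as had Ddx5 on the CPEB1 arrays. The sizes of their folds thus depend on the array background. Cds2, Zfp622, Zfp365 and Rpl34-ps1 were also among the 10 largest for CPEB4. Both rankings use the same IgG arrays, so a low IgG value favours a gene in both. In WT and HD, Cds2 stood at 10.85 and 10.24 in the input, above CPEB1 (10.17 and 8.74) and CPEB4 (8.58 and 9.29). Other probe sets of Wsb2 (3.08 and 2.41), Zfp622 (1.29 and 3.65, 2.71 and 0.98), Ppp1r12b (1.12 and 0.73, 1.56 and 0.62) and all 4 of Cds2 were above IgG in both pools, but not that of Eef1g (-0.09 and -0.16). That of Ddx5 had 0.48 and -0.55, and those of Pdlim5 1.06 and -0.50, -2.38 and -3.08, and -0.53 and -0.02. By limma 0 genes had an adjusted p under 0.05, the smallest being 0.121, while 836 had an unadjusted p under 0.05, 723 of them higher, against 567 by chance. IgG against input gave 1106 by the same test, so an excess over 567 also arose without a CPEB antibody. For CPEB1 over IgG the unadjusted split became 478 higher and 308 lower under cyclic loess, and 511 and 326 after quantile normalization.

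As groups, postsynaptic genes were higher with CPEB1 than with IgG in camera (median 0.64, adjusted p = 0.0247), among them Sipa1l1 (2.70 ± 0.85) and Agap2 (2.66 ± 0.58), which did not pass singly. Cytosolic ribosomal protein genes had a median of 0.95 (adjusted p = 1.25e-06), with Rps19 at 3.19 ± 0.50, and turned to -0.03 under cyclic loess. Nuclear long noncoding RNAs were lower (median -0.57, adjusted p = 0.0324), among them Snhg11 (-1.07 ± 0.30) and Malat1 (-0.87 ± 0.29). Against input the median of this list was 0.38 with CPEB1 and 0.74 with IgG, so it was lower than IgG but not lower than input. After quantile normalization the postsynaptic median was 0.31, the ribosomal median 0.58 and the noncoding RNA median was -0.84. With an estimated correlation the adjusted p was 0.653 for all 3, and under cyclic loess only the noncoding RNAs passed (adjusted p = 0.0252).

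Between the antibodies, 16 genes were lower with CPEB1 than with CPEB4 and 0 were higher. The largest were Fam76b (log2 -5.37 ± 0.24, adjusted p = 0.0212), Ivns1abp (-4.85 ± 0.40), Ddit4, a stress-induced inhibitor of mTOR signalling (-4.48 ± 0.33), Mettl6, a tRNA methyltransferase (-4.09 ± 0.26), Ugcg, which makes glucosylceramide (-3.98 ± 0.27), and Msl2 (-3.96 ± 0.25), with adjusted p up to 0.0441. Those 6 stood on the CPEB1 arrays between 2.69 and 5.69, and Fam76b, Ivns1abp and Ugcg below 4.23 on both, so the sizes of their differences depend on the array background. In the other direction Mmab came nearest (3.67 ± 0.38, adjusted p = 0.0555), before Tubg2 (2.73 ± 0.89), Ilrun (2.65 ± 0.65), Psmd6 (2.60 ± 0.32), Rgp1 (2.51 ± 0.31) and Ccm2 (2.46 ± 0.97), none of which passed. Over IgG the other 2 Mmab probe sets had -0.08 and 0.07 with CPEB1 against -0.67 and -0.51 with CPEB4, and 1.69 and -0.10 against -0.33 and 2.06. Unadjusted, 1740 genes had a p under 0.05 by limma, 1068 of them lower with CPEB1. The split was 351 higher and 1285 lower under cyclic loess, and 697 and 777 after quantile normalization.

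Poly(A) and 3′ end factors were lower with CPEB1 than with CPEB4 as a list (median -0.80, camera adjusted p = 4.81e-05), with 0 of 35 passing over all genes and 8 adjusted over the list alone, among them Cnot6 (-2.81) and Pum2 (-2.49). So were presynaptic (-0.80, 0.0052), medium spiny neuron (-0.39, 0.0052), postsynaptic (-0.68, 0.00559), astrocyte (-0.78, 0.0118), autism (-0.52, 0.0193), immediate early (-0.73, 0.0259) and oligodendrocyte genes (-0.58, 0.0353), given as median and adjusted p. After quantile normalization these medians were -0.43 for poly(A) factors, then -0.34, -0.06, -0.19, -0.63, -0.21, -0.59 and -0.33 in the order given. The median of all genes was 0.21 as deposited and 0.25 after quantile normalization, so each list stayed below it. With an estimated correlation none passed, at adjusted p = 0.434 for poly(A) factors and 0.653 for the other 7, and under cyclic loess only poly(A) factors did of these 8 (7.72e-05). Under cyclic loess oxidative phosphorylation genes (median 0.47, adjusted p = 0.0108) and ribosomal genes (0.21, adjusted p = 0.0391) passed as higher with CPEB1, the latter from a median of -0.24 as deposited. The 16 genes became 61 under cyclic loess and 75 with trended robust eBayes, and 0 after quantile normalization or without any 1 array.

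How far the antibodies and the pools gave like enrichment was compared across genes, which are not independent replicates. CPEB4 enrichment over IgG correlated between WT and HD at r = 0.574 (covariance 0.877), where simulated unchanged arrays gave 0.001, and CPEB1 enrichment at 0.206 (0.183). The value of 0.001 was fixed in advance, since the simulated arrays of the 2 pools were drawn independently. CPEB1 and CPEB4 shared the IgG array of a pool, which alone gives r = 0.501 and a covariance of 0.284 in simulation. The observed values were 0.63 and 0.834 in WT and 0.478 and 0.491 in HD. Across pools, with no shared IgG array, r was 0.339 for CPEB1 in WT with CPEB4 in HD (covariance 0.426) and 0.11 for CPEB1 in HD with CPEB4 in WT (0.119); the last turned to -0.024 with input in place of IgG. Of genes at 2-fold over IgG, 1627 were shared by the CPEB4 lists of WT and HD, against 637 for independent lists and 116 for simulated unchanged arrays, and 508 by those of CPEB1, against 188 and 116. CPEB1 and CPEB4 shared 1418 in WT (535 and 276) and 728 in HD (224 and 276), and across pools 1099 for CPEB1 in WT with CPEB4 in HD (478 and 116) and 505 for CPEB1 in HD with CPEB4 in WT (251 and 116). The simulated lists were not matched to the observed sizes, and the simulation had no difference in spread between fractions. The counts of 116 and 276 are therefore no expectation for lists of the observed sizes.

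The genes of the CPEB family and Htt, the gene of huntingtin, were followed in every fraction. Cpeb2 RNA stood at 7.94 in WT and 5.03 in HD on the CPEB4 arrays and at 3.17 to 3.38 on the other 6, which gave log2 4.71 and 1.76 over IgG with CPEB4 and 0.08 and -0.10 with CPEB1. Cpeb4 RNA likewise had 4.05 in WT and 0.98 in HD over IgG with CPEB4, and -0.01 and 0.27 with CPEB1. Cpeb1 had 0.02 and 1.95 with CPEB4. The IgG values of Cpeb2 (3.23 and 3.27) and Cpeb4 (3.32 and 3.48) lay below 4.23, so the sizes of these folds depend on the array background. These 3 and the thiamine transporter gene Slc19a3 (-0.55 and -0.03 with CPEB4) lay below the filter on mean expression and were not tested. Cpeb3 had 1.85 ± 0.62 with CPEB1 (adjusted p = 0.584) and 1.33 ± 0.62 with CPEB4 (adjusted p = 0.264), and Htt 0.29 ± 0.41 (0.952) and 1.11 ± 0.41 (0.203), none past the test.

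Whether binding differs in HD was addressed by enrichment within each genotype, where single arrays gave no replicate check. CPEB1 had 1966 genes at 2-fold over IgG and above input in WT and 706 in HD, and CPEB4 had 2672 and 2089. CPEB1 enrichment was lower in HD by most for Pacs2 (5.67 in WT, -6.56 in HD), Tlk1 (4.84, -4.46), Odf2 (5.16, -3.67), Tnpo2 (4.51, -3.49), Rpl32 (2.33, -4.99) and Slc25a23 (3.95, -3.35). It was higher in HD by most for Plagl2 (-2.82, 3.93), Ubfd1 (-0.65, 5.53), Pkig (-1.07, 4.98), the myelin gene Cnp (-2.81, 3.05), Laptm4b (-3.59, 1.86) and Rilpl1 (-1.56, 3.83). CPEB4 enrichment was higher in HD by most for Smad2 (-5.56, 2.13), the cytochrome oxidase gene Cox5a (-4.84, 1.76), Rusc2 (-2.50, 3.73), Usp7 (-0.06, 6.06), Miga2 (-3.50, 2.54) and Sugp2 (-1.41, 4.57). It was lower by most for Pacs2 (4.81, -2.02), Rrp7a (3.11, -3.43), Tmem245 (2.90, -3.44), Slc43a2 (2.70, -3.36), Rnf216 (2.45, -3.60) and Dtna (4.66, -1.27). In 23 of these 24 cases the IgG arrays themselves were at least 4-fold apart, and in 17 further apart than the RIP arrays. These 17 were all the CPEB4 cases and, with CPEB1, Pacs2, Ubfd1, Pkig, Cnp and Laptm4b. For the other genes named with CPEB1, the CPEB1 arrays were as far apart as the IgG arrays or further. Odf2, for example, stood at 10.36 in WT and 5.39 in HD on the CPEB1 arrays and at 5.21 and 9.06 on IgG. Pacs2 stood at 4.58 and 11.59 on the IgG arrays and at 9.39 and 9.58 on the CPEB4 arrays. Tlk1, Ubfd1, Pkig, Rilpl1, Smad2 and Usp7 lay below 4.23 on an IgG array, so the sizes of their differences depend on the array background.

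Of the 24 cases 17 had another probe set above the filter, and these differed the same way on average in 14, at least 2-fold in 6. Another Pacs2 probe set had 2.06 in WT and 0.54 in HD with CPEB1 but -0.12 and 1.11 with CPEB4. With CPEB4 the other 2 Cox5a probe sets were alike in both pools (3.28 and 3.47, 2.29 and 2.30), as were 2 of Usp7 (3.10 and 2.94, 3.23 and 2.67), while another of Usp7 had -0.04 and 6.59.

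In all, 1001 genes had CPEB1 enrichment at least 2-fold higher in HD and 2017 lower, and 1375 and 1617 for CPEB4. After quantile normalization the counts were 1517 and 1621 for CPEB1 and 1431 and 1299 for CPEB4, so the excess of lower genes shrank for CPEB1 and turned for CPEB4; for CPEB4 it also turned with the 75th percentile filter (1065 and 1018). With input in place of IgG the excess of lower genes grew, to 1126 higher and 2651 lower for CPEB1 and 1176 and 2247 for CPEB4. The input, though, was itself higher in HD at more genes than lower. The IgG arrays themselves differed at least 2-fold at 604 genes higher in HD and 1138 lower. Across genes the HD minus WT difference in enrichment correlated with that of IgG at r = -0.601 for CPEB1 and -0.727 for CPEB4, where unchanged arrays in simulation gave -0.707. Postsynaptic genes had a median CPEB4 difference of -0.59, at percentile 0 of matched random lists, and -0.26 after quantile normalization. The list's median CPEB4 enrichment itself hardly changed, at 1.17 in WT and 1.14 in HD, so a loss of enrichment as a group is not shown. Of 35, 9 were at least 2-fold lower in HD and 6 higher, with Sipa1l1 at -2.17 and Baiap2 at -2.15 but Nlgn2 at 3.65 and Camk2b at 2.68. With CPEB1 the median difference was -0.59 too (percentile 1.21), and -0.03 after quantile normalization, with a median enrichment of 0.92 in WT and 0.33 in HD. Both differences subtract the same IgG arrays, so the equal values are not independent results. Oxidative phosphorylation genes had a median CPEB4 difference of 0.93, at percentile 100, with Cox5a at 6.60, Ndufa3 at 5.19, Ndufa7 at 4.05 and Ndufv1 at 3.20, and 33 of 68 at least 2-fold higher in HD and 6 lower. With CPEB1 the median was -0.25 (percentile 36.6; 0.10 after quantile normalization), with 15 higher and 26 lower. The Ndufa3 difference comes from IgG, at 10 in WT and 3.62 in HD, since its CPEB4 values were 8.77 and 7.58. In the input the list was itself higher in HD, by a median of 0.79 (percentile 99.9), so a gain of binding is not shown.

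In the input, which carries the RNA levels of the 2 pools, markers of medium spiny neurons were lower in HD. Their median HD minus WT difference was -0.36, at percentile 0.01 of matched random lists (central range -0.13 to 0.59), and -0.72 under cyclic loess. At least 2-fold lower were 11 of 39, with Arpp21 (-2.53), the phosphodiesterase Pde1b (-2.50), the retinoid receptor Rxrg (-2.44) and Rgs4 (-2.16) the largest, and 3 were at least 2-fold higher. Penk, the proenkephalin gene, had -1.34, and the dopamine receptor genes Drd1 -0.06 and Drd2 0.49; these 3 were chosen after their values were seen. Oxidative phosphorylation genes had a median of 0.79 (percentile 99.9), with Ndufa3 at 5.26 and Ndufa5 at 4.85, neurodegeneration genes 0.64 (98.9) and cytosolic ribosomal protein genes 1.03 (96.2), with Rpl12 at 5.42 and Rpl39 at 4.66. Under cyclic loess and after quantile normalization these medians were 0.63 and 0.57 for oxidative phosphorylation, 0.40 and 0.38 for neurodegeneration and 0.19 and 0.56 for ribosomal genes. Astrocyte genes had a median of -0.33 (percentile 2.38) over members that went both ways, Gfap at 2.48 and Gja1 at 2.28 but Sparcl1 at -1.98 and Aldh1l1 at -1.16, and oligodendrocyte precursor genes -0.66 over 4 genes (1.49).

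Among single genes the input differed most upward in HD for Mrtfa (6.20), Sugp2 (5.89), Smo (5.63), Rpl12 (5.42), Cyb5r3 (5.39), Zfand3 (5.35), Ccl27a (5.32), Nucks1 (5.32), Ndufa3 (5.26) and Bub3 (5.21), in log2 HD minus WT. Downward the largest were Vmn1r48 (-6.47), Catsperd (-5.77), Rps15a-ps6 (-5.53), Hibadh (-5.46), Gpr37l1 (-5.28), Glb1 (-5.17), Sulf2 (-5.15), Kdm7a (-4.80), Tm2d2 (-4.63) and Speer8-ps1 (-4.56). The lower array stood below 4.23 for Mrtfa, Sugp2, Smo, Zfand3, Bub3, Vmn1r48, Catsperd, Rps15a-ps6, Hibadh and Kdm7a, so the sizes of these differences depend on the array background. At least 2-fold, 1277 genes were higher in HD and 503 lower, and 1101 and 791 after quantile normalization. Of the 20 named genes 9 had another probe set above the filter, and in 1 of these the others differed on average at least 2-fold the same way.

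**Figure D4:**
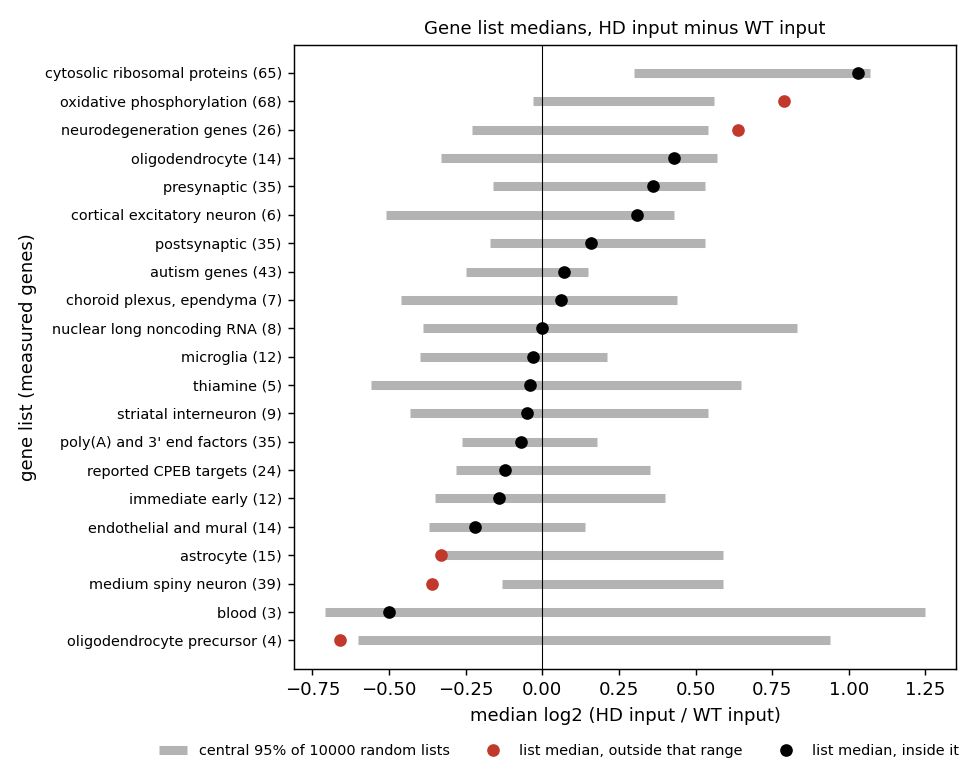
Median log2 HD input over WT input of each of the 21 gene lists (points, x axis), with the central 95% of 10000 random lists matched on mean expression as grey bars and the number of measured genes in brackets. Medium spiny neuron (-0.36), astrocyte (-0.33) and oligodendrocyte precursor genes (-0.66) lie below their bars, and oxidative phosphorylation (0.79) and neurodegeneration genes (0.64) above.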

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

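The tests of called genes in the lowest input quartile and of their fold after quantile normalization were chosen only after the result was seen, as were quantile normalization itself and the background shared by the pools. The other tests were set once the patterns were seen, but before their own values were.

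Genes whose enrichment over IgG had opposite signs in WT and HD stood out, with 1 array per group and the difference not tested. With CPEB1, enrichment turned from above IgG in WT to below it in HD for Pacs2 (HD minus WT -12.23), Tlk1 (-9.30), Odf2 (-8.83), Tnpo2 (-8.00), Rpl32 (-7.32) and Slc25a23 (-7.30), and the other way for Plagl2 (6.75), Ubfd1 (6.18), Pkig (6.05), Cnp (5.86), Laptm4b (5.45) and Rilpl1 (5.39). With CPEB4 it turned to below IgG for Pacs2 (-6.83), Rrp7a (-6.55), Tmem245 (-6.34), Slc43a2 (-6.06), Rnf216 (-6.05) and Dtna (-5.93), and to above IgG for Smad2 (7.69), Cox5a (6.60), Rusc2 (6.24), Usp7 (6.12), Miga2 (6.04) and Sugp2 (5.99). In 23 of these 24 cases the IgG arrays were at least 4-fold apart, and in 17 further apart than the RIP arrays. The 17 held every CPEB4 case but, with CPEB1, only Pacs2, Ubfd1, Pkig, Cnp and Laptm4b. With CPEB4 the other 2 Cox5a probe sets were alike in both pools. Presynaptic genes had a median CPEB1 enrichment of 0.81 in WT and -0.14 in HD (0.15 and -0.26 after quantile normalization), a difference of medians of -0.95; the median of the members' own differences was -0.38, within the random range (percentile 11.4), and -0.12 after quantile normalization. Oxidative phosphorylation genes had a median CPEB4 enrichment of -0.06 in WT and 0.84 in HD, a difference of 0.90. The median of the members' own differences was 0.93 (percentile 100), and the list was 0.79 higher in the HD input (percentile 99.9). With 1 array per group neither list was tested against replicates. For oxidative phosphorylation with CPEB4, other scalings gave -0.76 in WT and 0.07 in HD (cyclic loess), -0.88 and 0.04 (quantile normalization) and 0.10 and 1.0 (median centring). The level in each pool thus depends on the scaling. Among 6031 probe sets with no gene symbol, which the comparisons leave out, 120 were higher and 8 lower in CPEB4 RIP than in IgG RIP by limma over 22550 probe sets.

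The first pattern is that 1277 genes were higher and 503 lower, at 2-fold, in the HD input than in the WT input. Other probe sets of the same genes shifted the same way in 52.9% of 1240 cases. Loss or over-amplification of single RNA fragments on 1 array could give so low a share. The share does not decide it, since the other probe sets have lower means by the gene rule. The genes were also picked for a large difference between these same 2 arrays. For the medium spiny neuron list such fragment loss is argued against by the other probe sets of its genes, whose median HD minus WT difference was -0.39 (29 probe sets of 19 genes), at percentile 0.04 of random draws. The draws took probe sets singly, while some of the 29 share a gene, so that percentile may be too extreme. A change of the striatum in the HD pool stays open for that list, whose own median lay at percentile 0.01. A difference in dissection between the pools stays open too: cortical excitatory genes had a median of 0.31 (percentile 95.2) and oligodendrocyte genes 0.43 (93.8; -0.05 after quantile normalization), both within the random range.

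The second pattern is that 264 genes were higher and 5 lower in CPEB4 RIP than in IgG RIP. Fragment loss in single arrays is argued against as the whole cause, since other probe sets of the called genes were higher in both pools in 65.2% of 164 cases, against 43.2% of all other probe sets. Their median log2 was 1.24, against 2.91 for the called probe sets, so a part in the size of the folds stays open. A wider spread of the CPEB4 arrays could give the excess of higher genes, since 0 passed after quantile normalization. There the median adjusted p of the called genes by limma went from 0.0374 to 0.0918. Their fold went from 2.90 ± 0.35 to 2.27 ± 0.38 (median log2 and SE of 259 called genes). That does not decide whether spread gave the fold, since the genes were picked for a high value on these same arrays. A larger RNA yield stays open, with the ribosomal list at percentile 79.7 for its abundance. Of the 264 genes 93 were in the lowest input quartile and 81 in the highest, whose median over IgG was 0.60 against -0.18 in the lowest. This decides nothing, since the filter on mean expression used the CPEB4 arrays too and so favours genes of low input that are high with CPEB4. Binding by CPEB4 stays open, and no experiment without CPEB4 was analysed here.

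The third pattern is that CPEB1 had 1966 genes at 2-fold over IgG and above input in WT and 706 in HD. With input in place of IgG the counts were 2207 and 779, a ratio of 2.83, which decides little, since input was itself higher in HD at more genes than lower. A difference between the background arrays of the pools is argued against as the whole cause by setting both pools against the mean of the 2 IgG arrays and of the 2 inputs: the counts were 2063 and 673, a ratio of 3.07. A narrower spread of the HD CPEB1 array cannot be told apart from less binding: after quantile normalization the counts were 1174 and 775, a ratio of 1.51, with 1 array on each side. Less binding of CPEB1 in the HD pool stays open and untested.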

How the results depend on the processing

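Quantile normalization and a background shared by the pools were chosen after seeing the data; the other settings were not. Against IgG, CPEB1 had 0 genes under every setting run. For CPEB4 over IgG, 269 genes became 135 with the 75th percentile filter (fewer genes tested), 647 with all probe sets tested singly (more tests), 0 after quantile normalization, 0 with only the arrays of the 2 fractions (fewer arrays), and 0 to 274 when each array was left out: 274 without either CPEB1 array, 169 of them the same genes, and 0 without any other. It stayed within 1.5 times the count under the other settings, and 153 of the 277 genes with the mean of a gene's probe sets, 205 of 250 under cyclic loess, 257 of 303 under median centring and 224 of 348 with no genotype pool block were the same genes. For CPEB4 over input, 154 became 9 with that filter, 542 with all probe sets, 305 under cyclic loess, 239 with no block, and 0 after quantile normalization, with 2 fractions only or without any 1 array. For CPEB1 against CPEB4, 16 became 0 with that filter, 1 with the mean of a gene's probe sets, 170 with all probe sets, 61 under cyclic loess, 26 under median centring, 81 with no block, 75 with trended robust eBayes, and 0 after quantile normalization, with 2 fractions only or without any 1 array. For CPEB1 over input, 2 became 0 with all probe sets, median centring, trended robust eBayes, 2 fractions only or without any 1 array. For IgG over input, 3 became 9 under cyclic loess, 8 after quantile normalization, and 0 with all probe sets, trended robust eBayes, 2 fractions only or without any 1 array. Except where a number of tests or arrays is given, the cause was not tested. The genotype pool block already pairs the fractions of a pool. The planned search for the polyadenylation element and its alternatives were not run.

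For genes at 2-fold over IgG and above input, CPEB1 in WT went from 1966 to 1174 after quantile normalization and 1192 at 3-fold, CPEB1 in HD from 706 to 1197 at 1.5-fold and 405 at 3-fold, and CPEB4 in WT from 2672 to 1557 after quantile normalization and 1772 at 3-fold. For HD minus WT enrichment, CPEB1 higher in HD went from 1001 to 608 with the mean of probe sets, 1517 after quantile normalization, 2035 at 1.5-fold and 476 at 3-fold, and lower in HD from 2017 to 1217 at 3-fold. CPEB4 higher in HD went from 1375 to 1065 with the 75th percentile filter, 914 with the mean of probe sets, 2367 at 1.5-fold and 752 at 3-fold, and lower in HD from 1617 to 1018 with the 75th percentile filter, 2600 at 1.5-fold and 834 at 3-fold. Input higher in HD went from 1277 to 1928 at 1.5-fold and 735 at 3-fold, and lower in HD from 503 to 311 with the mean of probe sets, 791 after quantile normalization, 1561 at 1.5-fold and 229 at 3-fold.

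Correlations of enrichment with input in place of IgG, under cyclic loess and after quantile normalization were 0.083, 0.166 and 0.174 for CPEB1 between pools, 0.539, 0.536 and 0.504 for CPEB4 between pools, 0.707, 0.595 and 0.677 for CPEB1 with CPEB4 in WT, and 0.435, 0.45 and 0.539 in HD. CPEB1 in WT with CPEB4 in HD gave 0.257 and 0.27 under the last 2 settings. CPEB1 in HD with CPEB4 in WT reversed to -0.024 with input and was 0.073 under cyclic loess. Of gene lists past camera, 3 for CPEB1 over IgG became 1 under cyclic loess and 0 with an estimated correlation, and 8 for CPEB4 over IgG and 8 between the antibodies each became 3 and 0. Camera's direction reversed for 16 lists and settings, given here with the unadjusted camera value. Those under cyclic loess against IgG were ribosomal genes (0.819 with CPEB1; 0.01 with CPEB4, adjusted p = 0.0527), oxidative phosphorylation with CPEB4 (0.00709, adjusted p = 0.0496), interneurons (0.987 with CPEB1, 0.956 with CPEB4), and neurodegeneration (0.442), presynaptic (0.643) and oligodendrocyte genes (0.909) with CPEB1. Those between the antibodies were ribosomal (0.00559, adjusted p = 0.0391), reported CPEB targets (0.957), noncoding RNA (0.825) and interneurons (0.918). With no filter they were interneurons for CPEB1 over IgG (0.894) and oxidative phosphorylation between the antibodies (0.755), and with the mean of probe sets oligodendrocyte genes for CPEB1 over IgG (0.427) and oxidative phosphorylation between the antibodies (0.948). Among named genes, the input difference of Ccl27a reversed to -0.74 after quantile normalization and that of Tm2d2 to 0.21 with the mean of probe sets. Of the values of named genes and lists under the alternatives, 913 kept their direction and side of the threshold, 255 fell short of it with the direction kept, 15 passed it newly and 18 reversed; the input difference of Zfand3 dropped to 0.63 with the mean of probe sets. What signal over background limits is the weak genes: 17097 genes had a probe set, and 11345 lay above the filter.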

Other observations

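The counts over pairs of arrays, and the genes named here from them, were chosen only after the result was seen; the test of genomic span was not. A group of 69 genes stood at least 4-fold higher on both CPEB4 arrays than on any of the other 6. Fam76b had at least 8.16 with CPEB4 and at most 3.31 elsewhere, Ivns1abp 7.90 and 4.17, Siva1 10.01 and 6.42, and Mettl6 9.34 and 5.38, on the log2 scale. Other members, picked by eye, were Hnrnpk (8.01 and 5.23), G3bp1, a core protein of stress granules (7.42 and 4.66), Rbms3 (7.08 and 3.93), Msi2 (7.58 and 5.17) and the splicing factor Srsf4 (7.89 and 5.73). So were the transcription factor genes Mef2c (6.81 and 4.67), Ets2 (9.17 and 6.43), Zeb1 (7.69 and 5.57) and Sp4 (7.22 and 5.17), and the synaptic genes Gabra2 (7.66 and 4.61), Erc2 (6.55 and 3.61) and Syt4 (8.16 and 6.07). Whether any class of genes is in excess in this group was not tested.

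Of the 28 pairs of the 8 arrays none other had as many: the next, CPEB1 and CPEB4 of WT, had 11, and the pairs of CPEB1, IgG and input arrays had 2, 1 and 2. After quantile normalization the CPEB4 pair had 28 and the next 3.

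A hypothesis is a preference of CPEB4 RIP for long transcripts. In the RefSeq gene table the genes higher in CPEB4 RIP than in IgG RIP had a median genomic span of 29 kb, against 19.8 kb for random genes matched on mean expression (central range 16.2 to 24.1), at percentile 100 of 10000 draws. Span counts introns and stands only loosely for transcript or 3′ untranslated length, which was not analysed here.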
